A study of Mus musculus with 4 samples.

How the data were processed

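RNA from sorted subcutaneous adipocyte progenitor cells of 2 wild-type and 2 Adamts1 transgenic samples was extracted, labelled with Cy3 by the low input single-colour kit and hybridised to Agilent mouse arrays, per the labels' protocols. The deposited scanner files were written by Agilent Feature Extraction 10.7.3.1 on array design 028005, with probe coordinates on mm9, per the file headers. All 4 arrays were on 1 slide and in 1 scan, so neither can be told from the rest of the data and no block for them was fitted.

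The processed intensity that the authors deposited for each spot is background-subtracted and detrended within the array, with surrogate values where a spot did not exceed background, per the file headers. The raw spot and background intensities in the same files were used for 1 kind of alternative. The series value table that the authors deposited holds log2 values whose making is not given in the sources used here. Set against the scanner values, its 4 columns correlated at 0.9996 to 0.9999 with the log2 processed signal after a 75th percentile shift and centring of each probe on its median over the arrays, and column medians were 0.195, -0.021, -0.045 and 0.019. Its scale and centring are thus known from this comparison alone. It was used as an alternative, with the mean level of each probe added back so that a trend could be fitted.

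Control spots and spots marked as non-uniform or population outliers were left out, and the spots of a probe were averaged on the log2 scale, which left 56 probes without a value on some array. Each array's 75th percentile of log2 processed signal over non-control probes was subtracted. Names were updated through RefSeq accessions without versions, using a RefSeq gene table of assembly GRCm38.p6 for names alone, which named 26582 probes, 2892 of them by another symbol than in the array design, and 29099 probes kept the design's name. Exon and untranslated region annotation on mm9 was not used here. A gene entered by its probe with the highest mean over the 4 arrays, and a feature was tested if that probe was well above background on every array of at least 1 group, which left 24518 features, 13637 of them with a gene symbol that is not a clone, predicted-gene or accession name. A feature that passed through 1 group alone was likely to be higher in that group, so counts and list tests lean that way. Of 90 called genes with several tested probes, 5 had probes of opposite sign.

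The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, 2-sided, residual degrees of freedom 2, prior degrees of freedom 3.34) with Benjamini-Hochberg adjustment over all features, and a feature was called at an adjusted p under 0.05. The median SE was 0.18 on the log2 scale, so that the 95% interval of a gene with this SE excludes no change from 1.36-fold on. Signal over background, not a count, sets what an array can measure, and 39 called features were not above background on either wild-type array and 5 on either transgenic array. Replicate spots of a probe had a median SD of 0.058 to 0.071 within an array, which does not tell whether the arrays hold separate samples.

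Before the data were examined, 50 gene lists were fixed from textbook knowledge, along with the tests, the alternatives and the rule for named genes. The rule took Adamts1 and Ptn, the 12 highest and 12 lowest called genes with a proper symbol that were well above background on both arrays of the brighter group, and per list the 4 members with the smallest p and the member with the highest level. Ptn was fixed because it was known to be of interest to the group that made these mice, so its choice was not blind. The rule selected 235 genes. The alternatives were computed for 133 of them, all 101 that were called and the uncalled ones that were picked for mention after their values were seen. Lists were tested with camera (preset correlation 0.01, at least 5 tested members, Benjamini-Hochberg over lists): 47 lists were tested, 15 were called higher and 12 lower. None of the 27 calls held with an estimated correlation, where the lowest adjusted p was 0.410. The rotation test fry, which asks whether a list's genes move on balance one way, called 2 lists, Wnt ligands and receptors (adjusted p = 0.0159) and smooth muscle and pericyte markers (adjusted p = 0.0186). Over the lists 926 genes were tested, 99 were called over all genes and 351 when adjusted over the list alone. The median and mean differed in sign for 5 lists: ADAMTS proteases, proteoglycans, fatty acid synthesis, osteogenic and chondrogenic genes, and Schwann cell markers.

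The fit was tested on simulated data for this comparison: 20 draws of 24518 features with noise drawn from the fitted trend and prior, and 200 genes changed, 50 per fold. It recovered 0.4% of genes changed 1.5-fold, 21.2% at 2-fold, 59.5% at 4-fold and 78.7% at 8-fold, with 4.55 false calls per draw. Each draw also shifted a fixed list by 0.5 on the log2 scale. The simulated genes were independent, so the draws say nothing about correlation within lists. All simulated arrays had the same noise per gene. In the real data the SD of the log2 difference was 0.577 between the wild-type arrays and 0.345 between the transgenic arrays. The recovery and false calls therefore hold for equal noise alone. Alternatives were quantile normalization, a median shift, normexp background correction with offset 50 under either normalization, no filter and a stricter filter on dim probes, no intensity trend, a robust prior, the mean of a gene's probes, the replicate number as a block, each array left out, the authors' value table, outlier spots kept, other list tests and an adjusted p of 0.1. Array weights were added after the data were seen.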

Results

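Gene expression was measured in adipocyte progenitor cells, the precursors of fat cells, sorted by flow cytometry from the subcutaneous fat of male FVB mice at 4 weeks of age and lysed without culture. There were 2 wild-type samples and 2 samples from mice carrying an Adamts1 transgene, each on 1 single-colour Agilent array. Adamts1 is a secreted metalloprotease that cleaves matrix proteoglycans. Each array carried 59305 non-control spots for 55681 probes, and 47.0% of these spots were well above background on wild-type array 1, against 55.5% on wild-type array 2, 57.0% on transgenic array 1 and 56.0% on transgenic array 2. The 75th percentile of the signal was 239, 333, 354 and 350 on the same arrays. Over the 24518 features tested, the Pearson correlation was 0.984 between the wild-type arrays and 0.994 between the transgenic arrays, against 0.977 for wild-type array 1 with either transgenic array and 0.984 for wild-type array 2 with either. The labels do not say that samples came from separate animals, so the p-values measure the spread between these samples. With 2 arrays per group the number of arrays limits the precision, and an exact permutation test of a single gene could not give a p below 0.333.

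The comparison of transgenic with wild-type samples asks which genes differ in progenitors of mice that carry the transgene. Pleiotrophin (Ptn), a secreted heparin-binding growth factor, was 15.2-fold higher in the transgenic samples (log2 difference 3.92 ± 0.28 SE, n = 2 per group, adjusted p = 0.0162). It was chosen beforehand because it was known to be of interest to the group that made these mice. Of 26 mature adipocyte genes 3 rose, among them the fatty acid transporter Cd36 at 7.20-fold and the fatty acid binding protein Fabp4 at 4.71-fold, and the nuclear receptor Pparg rose 2.66-fold, while the list of adipogenic transcription factors was not called. Of 21 markers of Dpp4-positive interstitial progenitors 5 fell, with Pi16 2.23-fold and Procr 1.94-fold lower, and of 27 macrophage and myeloid markers 19 rose, with Cd74 at 9.24-fold and Pf4 at 8.19-fold. Of those 27, 13 passed the filter on signal through the transgenic arrays alone, which favours a rise. The list test camera called the adipocyte, Dpp4-positive and macrophage lists, each of them with adjusted p = 0.410 with an estimated correlation. Of 27 lists called by camera the rotation test fry called 2, the Wnt ligands and receptors and the smooth muscle and pericyte markers. With an estimated correlation 0 were called. In all, 423 features passed an adjusted p of 0.05 in the limma fit, 237 higher and 186 lower in the transgenic samples, and 273 of them differed by at least 2-fold, 198 higher and 75 lower. The balance of directions depended on the scaling and the filter. Of the calls 56.0% were higher, against 65.2% with normexp correction and quantile normalization, 64.3% with quantile normalization alone, 49.8% with normexp correction, 49.7% with a median shift and 46.8% among probes above background on all 4 arrays. At an unadjusted p under 0.05 there were 4660 features, where chance gives 1225.9, and the groups did not overlap for 53.1% of features, where chance gives 33.3%. Features vary together, so a difference between arrays from any source moves many of them. These excesses therefore do not measure an effect of genotype. Without transgenic array 1 the count of calls was 90 and without transgenic array 2 it was 114, while without wild-type array 1 it was 1289 and without wild-type array 2 it was 3998. With 1 array left out, the residual variance comes from the intact pair alone, so these counts do not show which arrays carry a difference. The SD of the log2 difference was 0.577 between the wild-type arrays and 0.345 between the transgenic arrays, and the main fit pools both pairs. With no intensity trend in the variance model limma called 0 features, the lowest adjusted p lying just above the threshold, although 4124 had an unadjusted p under 0.05. Of the 101 called genes that the rule for named genes selected, 35 stayed called without transgenic array 1 and 33 without transgenic array 2, and 60 kept their call in every setting with all arrays that tested them, except the fit without an intensity trend. Of those 60, 51 were tested in each of these settings, since the filter for signal on all 4 arrays tested 83 of the 101.

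No difference in Adamts1 itself was detected. Its probe, at positions 85795044 to 85795103 of chromosome 16 in the mm9 build, gave normalised log2 signals of 6.65 and 6.73 in the wild-type samples and 6.77 and 6.82 in the transgenic samples (difference 0.11 ± 0.09 SE, 1.08-fold, 95% interval 0.916 to 1.27, adjusted p = 0.573). Over the scalings the Adamts1 difference ran from 0.07 with a median shift to 0.27 with quantile normalization, and it was called in none of them. The labels give neither the promoter of the transgene nor the cells that express it, and a probe outside the transgene's cDNA would check nothing. Both Ptn probes, at positions 36691376 to 36691435 and 36665663 to 36665722 of chromosome 6, were well above background on all 4 arrays and gave 15.2-fold and 15.1-fold. Of the 15 tested genes of pleiotrophin and midkine signalling, 2 rose over all genes and 4 rose when adjusted over the list alone. Besides Ptn these were the receptor phosphatase Ptprb (log2 difference 2.73 ± 0.25, adjusted p = 0.0246), and, over the list alone, midkine (Mdk, 1.28 ± 0.19, adjusted p over all genes = 0.0514) and syndecan 1 (Sdc1, 0.77 ± 0.12, adjusted p over all genes = 0.0512). That Ptprb belongs to this signalling rests on the fixed list alone, and RNA from endothelial cells was not tested as a source of its rise. The list was called higher by camera (median 0.05, or 0.02 with the gene not above background in wild-type samples at its bound, adjusted p = 0.0483), with adjusted p = 0.467 with an estimated correlation. That call was lost without wild-type array 1 (adjusted p = 0.0582) or wild-type array 2 (adjusted p = 0.146) and was made in 9 of the 13 settings with every array (adjusted p up to 0.0699), and the list's median ran from -0.0052 to 0.12 over the scalings. Without transgenic array 1 the median was 0.18 and without transgenic array 2 it was 0.0042. Endothelial and macrophage markers moved with this list, at medians of 1.25 and 2.68. With markers not well above background on both wild-type arrays at their lower bounds, these medians were 0.74 and 2.18. With normexp background correction the log2 difference of Ptprb was 1.80.

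**Figure D1:**
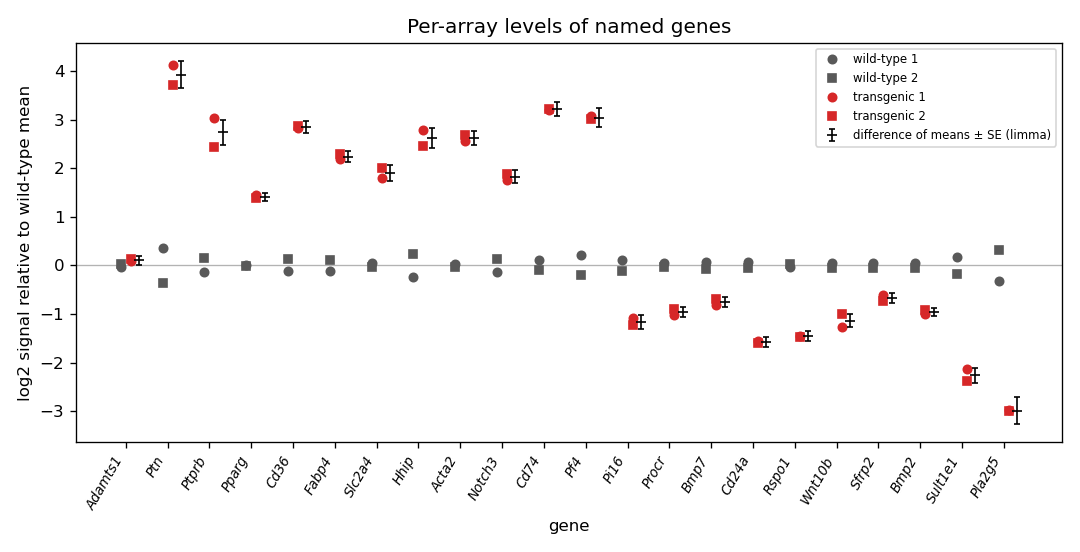
Normalised log2 signal of each array relative to the wild-type mean (vertical axis) for 22 genes (horizontal axis), with wild-type arrays in grey, transgenic arrays in red, and the difference of means with its SE from the limma fit in black. Adamts1 lies near 0 at 0.11, Ptn at 3.92, Pparg at 1.41 and Pi16 at -1.16.

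Among the 12 genes with the highest differences that a fixed rule selected, 11 were not well above background on either wild-type array. For these the fold is given as a lower bound, the transgenic mean against, per wild-type array, the higher of the probe's own signal and the lowest signal well above background. The same bound is given elsewhere for genes above background on 1 of 2 wild-type arrays. The bounds were at least 27.5-fold for Syt10, at least 26.6-fold for the immunoglobulin heavy chain gene Igh-VJ558, at least 19.5-fold for S100a9, at least 13.3-fold for Lilrb4a, at least 8.52-fold for the chemokine Ccl4, at least 6.51-fold for lysozyme 2 (Lyz2) and at least 6.30-fold for Ms4a7. They were at least 4.15-fold for Cyth4, at least 4.08-fold for Arhgap9, at least 3.16-fold for Wdfy4 and at least 2.92-fold for Il1b, and adjusted p values of these 11 genes in the limma fit ran from 0.0128 to 0.0477. The ranking and these adjusted p values used wild-type signals not well above background, so they do not show that these 11 changed most. Ngfr at 9.90-fold, Cd74 at 9.24-fold and Cd36 at 7.20-fold, above background on all 4 arrays, exceeded several of these bounds. Wild-type array 1 had the higher limit, so without wild-type array 2 the bounds were lower, 17.3-fold for Syt10, 16.8-fold for Igh-VJ558, 12.3-fold for S100a9, 8.37-fold for Lilrb4a, 5.36-fold for Ccl4, 4.09-fold for Lyz2 and 3.96-fold for Ms4a7. They were then 2.61-fold for Cyth4, 2.57-fold for Arhgap9, 1.99-fold for Wdfy4 and 1.84-fold for Il1b, and without wild-type array 1 all 11 were higher, with Syt10 at 43.7-fold. The bound of S100a9 was 11.8-fold without transgenic array 2 and 32.4-fold without transgenic array 1. The bounds hold for the probe used. Over the tested probes the log2 difference with all arrays ran from 1.80 to 4.47 for Lilrb4a and from 3.60 to 7.02 for Igh-VJ558. Without transgenic array 2 another of the 3 probes of Igh-VJ558 had the highest mean (log2 difference 1.44), while the probe used with all arrays gave 7.24 there. With a normexp correction that adds an offset of 50, the calls of Ms4a7, Arhgap9, Wdfy4, Cyth4 and Il1b were lost, and the log2 difference of Wdfy4 was 0.61 (adjusted p = 0.226). There Syt10 had a log2 difference of 2.61, S100a9 of 2.73, Lilrb4a of 1.82, Ccl4 of 1.37 and Lyz2 of 1.17. Ptn was the gene of the 12 that was measured above background in both groups. At the other end, Ttc21a was at least 5.94-fold lower and not well above background on either transgenic array. The phospholipase Pla2g5 was 7.93-fold lower, Myoc 5.98-fold, the melanocortin receptor accessory protein Mrap2 5.54-fold, the estrogen sulfotransferase Sult1e1 4.80-fold, Shisal1 4.62-fold, the interleukin 18 receptor Il18r1 4.58-fold and Acpp 4.49-fold lower. Gprasp2 was 3.69-fold, Col8a1 3.58-fold, Itgb7 3.58-fold and Pkp2 3.52-fold lower, and the adjusted p of these 12 genes lay between 0.0162 and 0.0443. With normexp correction and quantile normalization the log2 difference was -1.46 for Pla2g5, -1.26 for Mrap2, -0.78 for Acpp, -0.88 for Ttc21a and -1.19 for Pkp2. The calls of Pla2g5, Il18r1, Acpp and Col8a1 were lost there, and those of Il18r1 and Acpp with quantile normalization alone as well.

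Mature adipocyte genes were called higher as a list by camera but not by fry (adjusted p = 0.0506). Of 26 tested, 3 rose over all genes and 13 rose when adjusted over the list alone, with a median log2 difference of 0.72, or 0.60 with bounds (camera adjusted p = 6.00e-08, and adjusted p = 0.410 with an estimated correlation). With normexp correction the list kept its call with a median of 0.20, or 0.31 under quantile normalization. The 3 were Cd36 (2.85 ± 0.12 SE, adjusted p = 0.0128), Fabp4 (2.24 ± 0.11, adjusted p = 0.0128) and the insulin-responsive glucose transporter Slc2a4 (1.90 ± 0.16, adjusted p = 0.0226). The lipid droplet protein Plin1 had a difference of 2.30 (adjusted p = 0.0591) and lipoprotein lipase Lpl of 0.59 (adjusted p = 0.0707), which did not pass over all genes. Markers of Icam1-positive committed preadipocytes were also higher: 6 of 20 rose over all genes and 12 when adjusted over the list alone (median 0.60, camera adjusted p = 7.42e-10, and adjusted p = 0.410 with an estimated correlation). They included Cd36 and Fabp4, counted above among the mature adipocyte genes too. The others included Pparg (1.41 ± 0.08, adjusted p = 0.0156), the oxygenase Fmo1 (1.09 ± 0.10, adjusted p = 0.0246) and the basement membrane collagen Col4a1 (0.82 ± 0.12, adjusted p = 0.0490). Of the 20, 11 stand in another of the fixed lists too, and so do 10 of the 26 mature adipocyte genes. Cd36, Fabp4 and Lpl stand in both of these lists, so the 2 calls are not separate findings. Of 22 adipogenic transcription factors, Pparg and Egr2 (1.03 ± 0.11) rose and Ebf2 (-0.73 ± 0.08) fell, 4 rose and 2 fell when adjusted over the list alone, Cebpa had a difference of 0.61 (adjusted p = 0.0989). The factors were not called as a list (median 0.04, or -0.049 with normexp correction, adjusted p = 0.615). Endothelial and macrophage markers moved with these groups, at medians of 1.25 and 2.68, or 0.74 and 2.18 with bounds.

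Markers of Dpp4-positive interstitial progenitors, cells described as an early stage of the lineage, were lower. Of 21 tested, 5 fell over all genes and 18 fell when adjusted over the list alone (median -0.71, camera adjusted p = 1.00e-11, and adjusted p = 0.410 with an estimated correlation). Pi16 fell by 1.16 ± 0.15 (adjusted p = 0.0384), Procr by 0.96 ± 0.10 (adjusted p = 0.0270), Bmp7 by 0.76 ± 0.10 (adjusted p = 0.0411) and the alarmin Il33 by 1.06 ± 0.15 (adjusted p = 0.0477). Of 23 genes of adipocyte progenitor and fibroblast identity, 3 fell over all genes, and 4 rose and 7 fell when adjusted over the list alone (median -0.27, camera adjusted p = 0.0239, and adjusted p = 0.506 with an estimated correlation). The 3 were the surface protein Cd24a (-1.58 ± 0.11), the ectonucleotidase Nt5e (-1.02 ± 0.09) and the matrix protein Fbln1 (-0.85 ± 0.08), while Cd44 had a difference of 0.60 (adjusted p = 0.0677). The identity list was not called without wild-type array 1 (median -0.13, adjusted p = 0.137), without transgenic array 1 (adjusted p = 0.0609) or with quantile normalization (median -0.027, adjusted p = 0.337). Without wild-type array 2 its median was -0.44. It was called in 10 of the 13 settings with every array (adjusted p up to 0.361). Markers of Cd142-positive regulatory progenitors were higher, with 3 of 16 called over all genes, and 7 higher and 1 lower when adjusted over the list alone (median 0.44, camera adjusted p = 0.00394, and adjusted p = 0.506 with an estimated correlation). The 3 were Meox1 (1.53 ± 0.17), biglycan (Bgn, 1.05 ± 0.14) and Peg3 (1.41 ± 0.20), and without wild-type array 1 this list was not called (median 0.26, adjusted p = 0.0515). Macrophage markers were higher in the same samples, at a median of 2.68, opposite to the Dpp4-positive and identity lists.

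**Figure D2:**
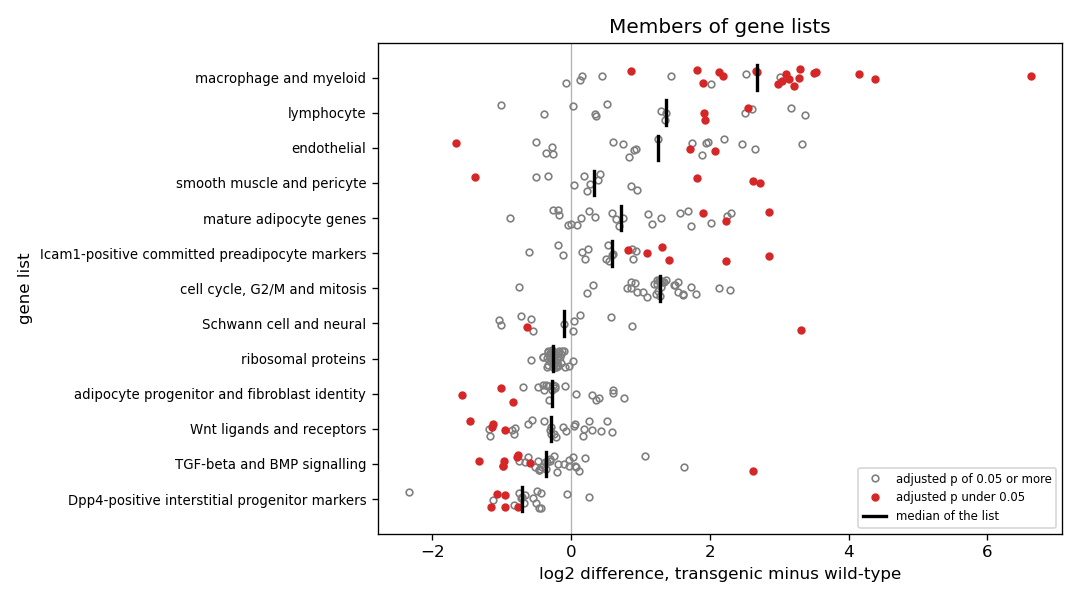
Log2 difference of each tested member, transgenic minus wild-type (horizontal axis), for 13 fixed gene lists (vertical axis). Filled red points had an adjusted p under 0.05 over all genes, open grey points did not, and the black bar is the list's median, which was 2.68 for macrophage and myeloid markers and -0.71 for markers of Dpp4-positive progenitors.

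Wnt ligands and receptors were lower on balance. Of 28 tested, 4 fell over all genes, and 1 rose and 9 fell when adjusted over the list alone (median -0.29, camera adjusted p = 0.00160, and adjusted p = 0.410 with an estimated correlation). Those that fell were the Wnt amplifier Rspo1 (-1.46 ± 0.10, adjusted p = 0.0162), Wnt9a (-1.12 ± 0.10, adjusted p = 0.0227), Wnt10b (-1.14 ± 0.13, adjusted p = 0.0315) and Wnt2 (-0.95 ± 0.14, adjusted p = 0.0499). The call of the ligands and receptors was lost without wild-type array 2 (adjusted p = 0.0635), and their median was -0.18 without transgenic array 2. Secreted Wnt antagonists were lower too, with 2 of 7 called over all genes, and 2 higher and 5 lower when adjusted over the list alone (median -0.48, camera adjusted p = 0.0347, and adjusted p = 0.467 with an estimated correlation). Those 2 were Sfrp2 (-0.67 ± 0.10) and Sfrp4 (-0.84 ± 0.12), and Dkk2 had a difference of -1.08 (adjusted p = 0.0750). The antagonists' call was lost without wild-type array 1 (adjusted p = 0.136) or wild-type array 2 (adjusted p = 0.137), and it was made in 10 of the 13 settings with every array (adjusted p up to 0.0819). Genes described as targets of Wnt and beta-catenin went both ways: of 22 tested, Ccn4 rose (1.13 ± 0.16, or 0.65 and not called with normexp correction), Ccn5 (-1.09 ± 0.15) and Sfrp2 fell, 5 rose and 8 fell when adjusted over the list alone. Camera did not call the list (median -0.23, adjusted p = 0.303). Of 21 anti-adipogenic regulators, Gli1 rose and Klf3 (-0.82 ± 0.09) and Id3 (-0.78 ± 0.10) fell, with 5 higher and 5 lower when adjusted over the list alone. As a list they were not called (adjusted p = 0.365). Macrophage, endothelial and mural markers were higher in the same samples, at medians of 2.68, 1.25 and 0.33, opposite to the Wnt ligands and antagonists. With bounds these medians were 2.18, 0.74 and 0.33.

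Genes of TGF-beta and BMP signalling were called lower as a list by camera but not by fry (adjusted p = 0.0506), with 1 of 35 higher and 6 lower over all genes, and 3 higher and 18 lower when adjusted over the list alone (median -0.36, camera adjusted p = 9.67e-06, and adjusted p = 0.410 with an estimated correlation). The ligand Bmp2 fell by 0.96 ± 0.09 (adjusted p = 0.0246) and Id3, a target of BMP signals, by 0.78 ± 0.10, while smooth muscle actin Acta2 rose by 2.62 ± 0.14 (adjusted p = 0.0128). Of 12 Hedgehog genes, the pathway's transcription factor Gli1 (1.59 ± 0.15) and its target Hhip (2.62 ± 0.20) rose, with 4 higher and 2 lower when adjusted over the list alone (median 0.17, or 0.05 with bounds, camera adjusted p = 0.0483, and adjusted p = 0.467 with an estimated correlation). That call was lost whichever array was left out, at an adjusted p of 0.0547 to 0.169, and the median without wild-type array 1 was -0.0064. Over the scalings the Hedgehog median ran from 0.024 to 0.21, and it was -0.027 with no filter and 0.51 with the mean of a gene's probes. It was made in 8 of the 13 settings with every array (adjusted p up to 0.166). Of 14 Notch genes, Notch3 rose (1.82 ± 0.13, adjusted p = 0.0176) and Lfng, above background on 1 of 2 wild-type arrays, was at least 2.28-fold higher without passing (adjusted p = 0.0502), with 5 higher and 3 lower when adjusted over the list alone. The list test gave no call (median 0.28, or 0.21 with bounds, adjusted p = 0.0918). Without transgenic array 2 the Notch list was called (median 0.73, adjusted p = 0.0426), and without transgenic array 1 its median was -0.043. Among the 13 settings with every array it was called in 2, with no filter and with the mean of a gene's probes, and its median was -0.087 among probes above background on all 4 arrays. Of 37 genes of FGF, PDGF, IGF and EGF signalling, Fgf10 (1.41 ± 0.10) and the feedback inhibitor Spry1 (0.95 ± 0.09) rose and Pdgfc fell (-1.11 ± 0.10), with 11 higher and 8 lower when adjusted over the list alone. No call was made for the list (adjusted p = 0.461). Of 21 regulators of angiogenesis secreted by stroma, Sema3d fell (-1.43 ± 0.17), Thbs1 had a difference of 1.73 (adjusted p = 0.0512), 2 were higher and 8 lower when adjusted over the list alone, and the list was called lower (median -0.14, adjusted p = 0.0210, and adjusted p = 0.410 with an estimated correlation). The angiogenesis median was -0.30 without wild-type array 1 and -0.081 with normexp correction. This call was lost without wild-type array 2 (median -0.28, adjusted p = 0.249) and made in 11 of the 13 settings with every array (adjusted p up to 0.109). Macrophage and endothelial markers were higher in the same samples, at medians of 2.68 and 1.25, opposite to the TGF-beta and angiogenesis lists. With bounds these medians were 2.18 and 0.74. Acta2 and Notch3 also stand in the list of smooth muscle and pericyte markers. Camera called that list higher (median 0.33, and adjusted p = 0.410 with an estimated correlation), with a call that depended on wild-type array 2.

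Matrix genes went both ways. Of 21 ADAMTS proteases and their inhibitors, Adamts17 (2.02 ± 0.21, or 1.19 with normexp correction, adjusted p = 0.0280) and Adamts9 (1.74 ± 0.18, adjusted p = 0.0280) rose and Adamts16 fell (-1.38 ± 0.16, adjusted p = 0.0343), with 5 higher and 6 lower when adjusted over the list alone. The median of this list was -0.06, or 0.10 with quantile normalization, its mean was 0.13, and it was not called (adjusted p = 0.786). Of 26 proteoglycan and hyaluronan genes, which include ADAMTS substrates, fibromodulin (Fmod, 2.70 ± 0.18) and Bgn rose and Omd fell (-0.74 ± 0.10), with 4 higher and 2 lower when adjusted over the list alone. Its median was -0.22, or -0.079 with normexp correction and quantile normalization, its mean was 0.03, and it was not called (adjusted p = 0.686). Of 22 collagens, Col18a1 (1.04 ± 0.08) and Col4a1 rose and Col12a1 (-1.41 ± 0.13) and Col8a1 (-1.84 ± 0.23) fell, with 7 higher and 4 lower when adjusted over the list alone. Camera did not call the list (adjusted p = 0.379) except with normexp correction and quantile normalization (adjusted p = 0.0433). Of 29 genes of collagen processing and elastic fibres, Fbln1 fell, Pcolce2 had a difference of -0.82 (adjusted p = 0.0552), 5 were higher and 7 lower when adjusted over the list alone, and the list was called lower (median -0.26, adjusted p = 0.0253, and adjusted p = 0.467 with an estimated correlation). Under quantile normalization the median was -0.14, or -0.11 with normexp correction added. Their call was lost without wild-type array 1 (median -0.15, adjusted p = 0.136), wild-type array 2 (adjusted p = 0.0777) or transgenic array 1 (adjusted p = 0.0718), and it was made in 8 of the 13 settings with every array (adjusted p up to 0.370). Of 10 matrix metalloproteinases, Mmp17 rose (0.89 ± 0.13), 3 were higher and 3 lower when adjusted over the list alone. As a list they were not called (median 0.17, or 0.03 with bounds and -0.014 with normexp correction, camera adjusted p = 0.366). With 1 array left out their median ran from -0.076 to 0.34. Macrophage and endothelial markers were higher in the same samples, at medians of 2.68 and 1.25, or 2.18 and 0.74 with bounds.

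No single gene of the cell cycle lists passed over all genes, but both lists were higher. Of 33 tested genes of G2/M and mitosis, 26 were higher when adjusted over the list alone (median 1.28, or 1.25 with bounds, camera adjusted p = 5.52e-14, and adjusted p = 0.506 with an estimated correlation). Relative to the wild-type mean, the median of the list was 0.80 on transgenic array 1 and 1.73 on transgenic array 2, and the correlation among its members was estimated at 0.837. Without transgenic array 2 the median was 0.81, and with normexp correction it was 0.85. The DNA topoisomerase Top2a had a difference of 1.73 ± 0.32, or 1.14 with normexp correction (adjusted p = 0.0765), and Kif4 was at least 2.52-fold higher, or 1.58-fold without wild-type array 2 (adjusted p = 0.0549). Of 32 genes of G1/S and DNA replication, 8 were higher when adjusted over the list alone (median 0.39, camera adjusted p = 1.93e-08, and adjusted p = 0.467 with an estimated correlation), with Chaf1b at 0.90 (adjusted p = 0.0560). Without wild-type array 1 the G1/S median was 0.61. Macrophage, lymphocyte and endothelial markers moved with the cell cycle lists, at medians of 2.68, 1.36 and 1.25, or 2.18, 0.80 and 0.74 with bounds. Of 23 cyclin-dependent kinase inhibitors and p53 targets, none passed over all genes, 1 was higher and 1 lower when adjusted over the list alone, and the bound for Cdkn2a was 1.44-fold, or 0.907-fold without wild-type array 2 (adjusted p = 0.0548). The list test gave no call (adjusted p = 0.234). Ribosomal protein genes were lower by a small amount, with 0 of 45 called by either adjustment, 44 of 45 below the wild-type mean and Rps15 at -0.58, adjusted p = 0.129 (median -0.26, camera adjusted p = 7.73e-08, and adjusted p = 0.506 with an estimated correlation). Their median was -0.14 without wild-type array 1 and -0.39 without wild-type array 2, and with quantile normalization it was -0.041 and not called (adjusted p = 0.0646). The ribosomal list was called in 11 of the 13 settings with every array (adjusted p up to 0.0825).

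Markers of other cell types differed between the groups. Of 27 tested macrophage and myeloid markers, 19 rose over all genes and 24 when adjusted over the list alone (median 2.68, or 2.18 with the 13 markers not well above background on both wild-type arrays set to their bounds, camera adjusted p = 2.25e-24, and adjusted p = 0.410 with an estimated correlation). Those 13 entered the test through the transgenic arrays alone, as did 6 of the lymphocyte and 9 of the endothelial markers below. For these the filter favoured a rise. Among 12 low-level macrophage markers above background on all 4 arrays the median was 2.43. The antigen presentation genes Cd74 (3.21 ± 0.14, adjusted p = 0.0128) and H2-Aa (at least 10.1-fold, adjusted p = 0.0128, above background on 1 of 2 wild-type arrays) rose, as did the complement gene C1qc (at least 7.92-fold, adjusted p = 0.0162, above background on 1 of 2 wild-type arrays) and Pf4 (3.03 ± 0.20, adjusted p = 0.0162). Itgam, the member with the highest signal, had a difference of -0.07 (adjusted p = 0.708), and of 0.0018 with quantile normalization. With normexp correction the median was 1.17 and the list kept its call. The log2 differences of H2-Aa and C1qc were then 1.62 and 1.48. Of 16 lymphocyte markers, Lck (1.93 ± 0.21), Ltb (1.91 ± 0.24) and Cd3d (at least 3.34-fold, or 2.10-fold without wild-type array 2) rose, and 11 were higher and 1 lower when adjusted over the list alone (median 1.36, or 0.80 with bounds, camera adjusted p = 2.15e-06, and adjusted p = 0.410 with an estimated correlation). With normexp correction the lymphocyte median was 0.33, Lck had a difference of 1.09, and the calls of Cd3d and Ltb were lost. Cd3e, of the same receptor complex as Cd3d, had a difference of -1.01, or -0.57 without wild-type array 2 (adjusted p = 0.162). Of 21 endothelial markers, Egfl7 (2.08 ± 0.24) and Mmrn2 (1.71 ± 0.22) rose and Ecscr fell (-1.66 ± 0.17), Vwf had a difference of 2.20, or 1.28 with normexp correction (adjusted p = 0.0591), and 13 were higher and 2 lower when adjusted over the list alone (median 1.25, or 0.74 with bounds, camera adjusted p = 0.000118, and adjusted p = 0.410 with an estimated correlation). With normexp correction the endothelial median was 0.36, and among probes above background on all 4 arrays it was 0.67 and the call was lost (adjusted p = 0.0575).

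Of 14 smooth muscle and pericyte markers, Acta2, Notch3 and Rgs5 (at least 4.91-fold, or 3.24-fold without wild-type array 2) rose and Kcnj8 fell (-1.38 ± 0.18), with 4 higher and 2 lower when adjusted over the list alone (median 0.33, camera adjusted p = 0.00510, and adjusted p = 0.410 with an estimated correlation). The mural call was lost without wild-type array 2 (adjusted p = 0.0609), and with normexp correction the median was 0.16 and the call of Rgs5 was lost. Of 9 erythroid and platelet genes, Pf4 rose and Tfrc had a difference of 0.59 (adjusted p = 0.233), with 1 higher when adjusted over the list alone (median 0.71, camera adjusted p = 0.00340, and adjusted p = 0.410 with an estimated correlation). Over the alternatives the difference of Tfrc ran from 0.26 to 0.79. The erythroid call was lost without wild-type array 2 (median 0.36, adjusted p = 0.108), and the median was 1.37 without wild-type array 1, 1.35 without transgenic array 1 and 0.45 without transgenic array 2. Schwann cell and neural markers were not called as a list (median -0.11, or 0 with bounds, mean 0.02, adjusted p = 0.606), although of the 13 tested the neurotrophin receptor Ngfr rose (3.31 ± 0.43) and Mbp fell (-0.63 ± 0.09), with 2 higher and 2 lower when adjusted over the list alone. Of 10 epithelial and keratinocyte markers, the prolactin receptor Prlr rose (1.85 ± 0.13) and Krt19 (-0.74 ± 0.10) and Cldn3 (-1.10 ± 0.15) fell, with 1 higher and 3 lower when adjusted over the list alone. No call was made for the list (adjusted p = 0.303). Of 5 mesothelial markers, Cldn15 rose (0.87 ± 0.11) and Krt19 fell, Il18 had a difference of -0.58 (adjusted p = 0.0754), 1 was higher and 3 lower when adjusted over the list alone. Camera did not call the list (adjusted p = 0.0891).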

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

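Array weights were chosen after seeing the data, and all other settings before. The sign of the Adamts1 difference and its failure to pass held in the 13 settings with every array and the 4 without 1 array. With every array, 60 of the 101 called genes named by the rule kept their call in every setting that tested them except the fit with no intensity trend. None of the 101 turned direction in a setting that tested it. The settings use the same arrays that gave the calls, so a kept direction is no separate support. Signal over background limits what can be said of dim genes, whose differences the offset of the normexp correction shrinks by construction. Without the intensity trend limma called 0 genes and 0 with at least a 2-fold change, with 4124 at an unadjusted p under 0.05, and 223 list members over the list alone, against 423, 273 and 351. With no filter on dim probes 695 genes were called and the median within-group correlation was 0.974. Normexp with quantile normalization gave 149 genes with at least a 2-fold change. At an adjusted p of 0.1 there were 1130 calls. Array weights gave 440 calls. The cause of these differences was not tested.

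Deviations of same-numbered arrays correlated at 0.0032. Over 2 pairs this gave no sign that the replicate numbers pair the samples, but it cannot exclude it. With the number as a block 774 genes were called, 435 of them with at least a 2-fold change. Slide and scan blocks were not run because all arrays shared 1 slide and 1 scan.

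Camera called 27 lists, 0 with an estimated correlation, and fry called 2. Leaving out each array in turn, where the lone array is assumed to vary like the other group, gave 90 to 3998 calls, 90 to 2533 with at least a 2-fold change, 17 to 24 lists, 199 to 447 list members over the list alone and a within-group correlation of 0.982 to 0.993. Calls fell to 90 without transgenic replicate 1 and 114 without transgenic replicate 2, and rose to 1289 without wild-type replicate 1 and 3998 without wild-type replicate 2. The 423 calls kept their direction in all 4. A call from the same arrays makes this likely in advance, so it is no separate support.

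Lists that camera did not call turned direction relative to other genes in some settings. Camera set that direction, so the mean log2 difference, given here, need not change sign. In the main fit the mean was 0.028 for proteoglycans, -0.057 for oxidative phosphorylation, 0.66 for Notch genes, 0.022 for Schwann cell markers and 0.13 for ADAMTS proteases. Proteoglycans gave 0.10 with quantile normalization, 0.032 and 0.086 with normexp under a percentile shift and quantile normalization, 0.015 with no filter, 0.031 with the strict filter and 0.0013 to 0.055 with an array left out. Oxidative phosphorylation gave 0.017, 0.0032 and 0.016 under the first 3 of these settings and -0.14 to 0.026 with an array left out. Under the strict filter Notch genes gave 0.086 and Schwann cell markers 0.13. With an array left out Schwann cell markers gave -0.34 to 0.12 and ADAMTS proteases 0.0085 to 0.27. Of uncalled genes near 0, Ddx3y gave -0.010 with a median shift and -0.23 to 0.28 with an array left out, and Itgam 0.0018 with quantile normalization, 0.0017 with normexp and quantile normalization and 0.058 with the mean of a gene's probes.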

Other observations

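All tests of explanations in this part were chosen after the result was seen. Several fixed lists outside the main account also differed. Of 39 chemokine and cytokine genes, 5 rose and 1 fell over all genes, and 14 rose and 6 fell when adjusted over the list alone (median 0.23, camera adjusted p = 0.0160, and adjusted p = 0.501 with an estimated correlation). That call was lost without transgenic array 2 (median 0.15, adjusted p = 0.101) and among probes above background on all 4 arrays (median 0.12, adjusted p = 0.428). Ccl6 (2.68 ± 0.24), Ccl9 (at least 6.68-fold, above background on 1 of 2 wild-type arrays), Ccl3 (at least 3.21-fold, or 2.02-fold without wild-type array 2) and Ccl4 rose, with Ccl6 at 1.63 and the call of Ccl3 lost with normexp correction. Of 34 interferon response genes, 0 were called by either adjustment, Oas2 had a difference of 1.36 (adjusted p = 0.0885), and the list was called higher (median 0.22, adjusted p = 0.000700, and adjusted p = 0.506 with an estimated correlation). This call was lost without transgenic array 2 (median 0.11, adjusted p = 0.112), and the median was 0.53 without transgenic array 1 and 0.36 without wild-type array 2. Of 24 genes of cholesterol synthesis, Hmgcs1 rose (0.61 ± 0.09), Sqle had a difference of 1.52 (adjusted p = 0.0743), 5 were higher when adjusted over the list alone, and the list was called higher (median 0.35, adjusted p = 0.00122, and adjusted p = 0.506 with an estimated correlation). The cholesterol median was 0.13 without wild-type array 1 and 0.57 without wild-type array 2. Macrophage markers, with a median of 2.68, moved with these lists.

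Of 25 genes of the unfolded protein and integrated stress response, Herpud1 (-0.87 ± 0.09), Trib3 (-0.90 ± 0.10) and Dnajc3 (-0.83 ± 0.12) fell, and 2 were higher and 9 lower when adjusted over the list alone (median -0.27, camera adjusted p = 0.000746, and adjusted p = 0.506 with an estimated correlation). Without wild-type array 2 this call was lost (adjusted p = 0.108). Of 17 heat shock genes, Hspb1 had a difference of -0.84 (adjusted p = 0.0533) and 4 were lower when adjusted over the list alone (median -0.17, camera adjusted p = 0.00405, and adjusted p = 0.506 with an estimated correlation). The heat shock call was lost without wild-type array 2 (adjusted p = 0.188) and with quantile normalization (median -0.044, adjusted p = 0.0577), and it was made in 10 of the 13 settings with every array (adjusted p up to 0.112). Of 28 genes of the immediate early and dissociation response, Egr2 and Nr4a2 (1.37 ± 0.19) rose and Zfp36 fell (-0.62 ± 0.09), 2 were higher and 6 lower when adjusted over the list alone, and the list was called lower (median -0.26, adjusted p = 0.0239, and adjusted p = 0.410 with an estimated correlation). Its median was -0.087 with quantile normalization, and -0.083 with normexp correction added. The call was lost whichever array was left out, at an adjusted p of 0.0628 to 0.137, and made in 8 of the 13 settings with every array (adjusted p up to 0.242). Of 21 glucocorticoid response genes, Sgk1 rose (0.63 ± 0.09) while the list was called lower (median -0.30, adjusted p = 0.0135, and adjusted p = 0.506 with an estimated correlation), and 1 was higher when adjusted over the list alone. Without wild-type array 1 the glucocorticoid call was lost (median -0.090, adjusted p = 0.278), with quantile normalization the median was -0.19, and the call was made in 9 of the 13 settings with every array (adjusted p up to 0.0978). Macrophage markers were higher in the same samples, while these 4 lists were called lower.

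Other fixed lists were not called. Of 22 hypoxia genes Hk2 rose (0.61 ± 0.09), and 1 was higher and 1 lower when adjusted over the list alone. The hypoxia list had an adjusted p of 0.366, and of 0.0471 with normexp correction. Of 11 brown and beige fat genes Cited1 rose (1.07 ± 0.11) and Ebf2 fell, 1 was higher and 2 lower when adjusted over the list alone, and the list had an adjusted p of 0.473. Of 13 osteogenic and chondrogenic genes Comp fell (-1.81 ± 0.21, or -1.18 with normexp correction and quantile normalization), 4 were higher and 1 lower when adjusted over the list alone, and the list had an adjusted p of 0.615. Oxidative phosphorylation had 0 of 43 called by either adjustment, Atp5d at -0.22 and a list adjusted p of 0.207. It was called lower with a median shift (adjusted p = 0.0471) and without wild-type array 2 (adjusted p = 0.00681). Fatty acid synthesis and storage had 0 of 23 called by either adjustment, Elovl6 at 0.58 and a list adjusted p of 0.473. Skeletal muscle genes had 0 of 12 called over all genes and 1 higher when adjusted over the list alone, Myl1 at 1.04 and a list adjusted p of 0.208. Over the alternatives the difference of Myl1 ran from 0.53 to 1.23. Lymph node stroma had 0 of 7 called by either adjustment and Cxcl13 at -0.46, with a list adjusted p of 0.486. Too few members for a list test were measured of mast cell genes (3 tested, Mcpt4 at least 1.94-fold higher, or 1.22-fold without wild-type array 2, with adjusted p = 0.0708), of sex-linked genes (3 tested, Ddx3y at 0.03 and Uty at -0.33) and of the transgene itself.

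The first pattern weighed is the rise of macrophage and myeloid markers. A lower share of progenitors would raise alike the markers of those other cell types that the sorts held. The 25 macrophage markers with a low wild-type level were set to their bounds where not above background on both wild-type arrays. Their median exceeded that of 75 low-level markers of all other fixed cell types, as measured, by 1.59 (95% bootstrap interval over genes 0.74 to 2.30). Among markers above background on all 4 arrays it did so by 2.05 (1.33 to 2.99). Macrophage markers thus rose more than this pool. The pool joins cell types that the sorts may not have held with endothelial and lymphocyte markers. The endothelial and lymphocyte medians were 1.25 and 1.36, or 0.74 and 0.80 with bounds, against 2.18 with bounds for the macrophage list. A bound limits a rise from below and does not give its size. The difference from this pool therefore cannot decide whether the share of progenitors was lower. The dimmer wild-type array 1 is argued against by the median without that array, 2.90. RNA from myeloid cells in the transgenic sorts cannot be told apart from regulation of these genes: 88.9% of the 27 markers were higher in both transgenic than in both wild-type arrays, among them Cd74 at 9.24-fold and Pf4 at 8.19-fold but not Itgam at -0.07, and that share restates the rise. Of the 27, 13 entered the test through the transgenic arrays alone, which by itself favours a high share. Genes are not independent replicates in these intervals. The sort for progenitors is meant to remove myeloid cells, and whether their number differed in the tissue or in the gate was not tested, so an effect of the genotype stays open.

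The second pattern is the fall of Dpp4-positive markers with the rise of Icam1-positive markers. Dilution of progenitor RNA by other cells would lower both progenitor lists alike only if those cells expressed neither. The Dpp4-positive median lay 0.43 below that of 23 identity genes (difference -0.43, 95% interval over genes -0.74 to -0.19). Whether other cells expressed identity genes was not tested, and Cd44, 1 of these genes, had a difference of 0.60. The unequal fall therefore cannot decide on dilution. Without the dimmer wild-type array 1 the median of the Dpp4-positive markers was -0.65. For the Icam1-positive part, RNA from fat, endothelial, mural or myeloid cells, which the sort for progenitors is meant to remove, cannot be told apart from a change in the progenitors, because the 6 markers not shared with such cells had a median of 0.71 with a 95% interval from -0.36 to 1.01. For the Dpp4-positive part dilution stays open. A shift of progenitors with genotype is another candidate explanation for that part, was not tested and stays a hypothesis.

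The third pattern is the rise of Ptn. A fault of 1 probe is argued against by the other probe, which gave 3.92, and the dimmer wild-type array 1 by the difference without it, 4.28. Schwann and other neural cells as the source would need markers with a similar wild-type level to rise about as much. The median of all tested neural markers was -0.11 (95% interval over genes -0.63 to 0.12). Several had a higher wild-type log2 level than Ptn (-1.90), such as Mbp at 2.42 and Pmp22 at 5.91, and would rise less. Ngfr, with a wild-type level of -1.32, rose by 3.31, and S100b had a difference of 0.88 (adjusted p = 0.0719 in the limma fit). The median therefore cannot decide on this source. Endothelial, mural and myeloid cells were not tested as a source of Ptn, so a change in the progenitors themselves may account for it but is not shown.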
